A study of Brassica rapa and Brassica rapa x Brassica nigra and Brassica nigra with 18 samples.

How the data were processed

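RNA was measured in 18 anther libraries of B. rapa (AA), B. nigra (BB) and their allohaploid (AB) at meiosis and at mitosis, with 3 libraries in each of 6 groups. Groups and replicate numbers came from the sample titles and the stage and genome labels. Per the labels' protocols, flower buds from meiosis and from tetrad to maturity were collected, RNA was extracted with Trizol and libraries were made with an Illumina protocol. The labels do not say that the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

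The authors deposited a table of raw counts per gene and a table of FPKM values. Per the submitters' processing notes, Bowtie 1.0.1, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0 were used. The roles of these tools, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. The count table held 79644 gene identifiers, of which 36454 named the A genome, 35686 the B genome and 7504 an unplaced sequence. Reads had therefore been assigned to the genes of both genomes at once, and reads of near-identical A and B copies can fall on either. Each deposited FPKM value equalled the count divided by a fixed length for the gene and by the library's total count, with a largest relative deviation of 5.32e-08. Of those lengths, 99.9% were multiples of 3, so they are coding lengths. The 12280 identifiers found only in the count table had 0 counts. A second column with the name of the first AA library at mitosis was identical to the first one, and this 1 column was not used.

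Library totals ran from 9782001 to 12161111 counts. A count of 0 over the 3 libraries of a group allows up to 3 counts. Intervals and floors of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

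Because AA has no B genome and BB no A genome, A genes were fitted with the AA and AB libraries and B genes with the BB and AB libraries. Library sizes and TMM factors came from the genes of that genome alone. This choice, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood F test on group means over all 4 groups of the fit, after the filter for low counts of edgeR by group. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. The counts changed at least 2-fold are given beside these. For each genome the 5 contrasts were AB against the parent at meiosis, AB against the parent at mitosis, the stage change in the parent, the stage change in AB, and the difference between both stage changes. Standard errors were derived from the F statistics. The common dispersion was 0.0075 for A genes and 0.00592 for B genes. BB against AA and AB against the mid-parent level were not run, because each parent lacks the genome of the other, its counts on genes of that genome are not levels of those genes, and pairs of A and B copies were not used here.

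Alternatives were DESeq2 1.42.0, relative log expression and upper-quartile factors, no filter on low counts, the replicate number as a block, only the groups of a contrast in the fit, library sizes from all genes, limma 3.58.1 on log2(FPKM + 1), a minimum of 2-fold, and leaving out each library in turn. After seeing the data, a further alternative left out genes that draw 10% or more of their parental CPM from the other parent. These genes were dropped from the fitted results, and scaling, fit and adjusted p-values were not computed again. Genes were grouped by their stage change in the parent, with 32-fold as the limit of the extreme groups, also after seeing the data. These group definitions use the same parental libraries at mitosis as the comparison with AB.

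None of the gene identifiers of the count table was found in a reference table of 51589 B. rapa genes (0 matches), so gene names were not used here. For this reason none of the 290 entries of 14 gene lists fixed beforehand could be matched, and no gene list was tested. The rule for naming genes then allowed at most 2 identifiers that rose and 2 that fell per contrast. These had the largest log2 changes among genes past the threshold, with at least 10 CPM in the higher group and a mean of at least 10 counts per library in the lower group. Values per gene are CPM after TMM scaling within the genome. For the level in the other parent, CPM of all counts, averaged over both stages, is given.

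The pipeline was tested on simulated data with 200 changed genes drawn from the real means and library sizes. For AB against AA at meiosis it recovered 41.8% of genes changed 1.5-fold, 68.7% at 2-fold and 84.8% at 4-fold, and it called 0.113% of unchanged genes. For AB against BB at meiosis the values were 47.0%, 62.7%, 87.9% and 0.0572%. In counts, 28, 46 and 56 changed genes were recovered for AB against AA, and 26 unchanged genes were called. For AB against BB these counts were 31, 42, 58 and 12. False calls were thus a much larger share of the calls than of the unchanged genes. In both simulated comparisons their share of the calls was above 0.05, the threshold set for the adjusted p. Far fewer genes were changed here than were called in the real contrasts, so the share of false calls there was not tested. Replicate numbers did not pair the libraries, since the deviations of libraries with the same number correlated between -0.03 and 0.03. Each library was counted as 1 replicate, as labelled. Libraries of a group differed by more than the sampling noise of independent reads. As far as each count is 1 such read, this argues against a library deposited under 2 names. It does not show that the libraries came from separate plants. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.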

Results

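The series measured messenger RNA in young anthers of 3 kinds of Brassica plant at 2 stages of male development. The plants were Brassica rapa (genome AA), Brassica nigra (genome BB) and a synthetic allohaploid (AB) from a cross with B. rapa as the mother and B. nigra as the father. An allohaploid carries 1 set of chromosomes from each of 2 species, so its chromosomes have no identical partner to pair with at meiosis. The stages are meiosis, when spore mother cells divide to form microspores, and mitosis, the later period in which microspores divide and become pollen. Each of the 6 combinations of genome and stage had 3 libraries. The 18 libraries held between 9782001 and 12161111 counts each. The question was how gene activity in AB anthers differed from that of each parent at each stage, which bears on the pollen fertility of the hybrid.

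The gene identifiers named the A genome, the B genome or an unplaced sequence. In AA, 92.5% ± 0.00137 of the counts at meiosis and 92.4% ± 0.144 at mitosis fell on A genes (SD, n = 3 libraries here and below). In BB, 84.2% ± 0.0260 at meiosis and 83.5% ± 0.0609 at mitosis fell on B genes. In AB, 49.1% ± 0.0223 of the counts at meiosis fell on A genes and 43.8% ± 0.0387 on B genes. The AB values at mitosis were 49.7% ± 0.0310 and 43.8% ± 0.0199. Unplaced genes took 3.42% of the counts in AA, 7.15% in AB and 10.9% in BB at meiosis.

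Both parental genomes were therefore expressed in the AB anthers at both stages. Of the AB counts that fell on A or B genes, A genes took 52.9% ± 0.033 at meiosis and 53.2% ± 0.013 at mitosis. The difference of 0.288 percentage points was larger than the spread between libraries. A two-sided exact permutation test gave p = 0.1, the smallest p that 3 libraries against 3 can give. The share at meiosis was 53.6% without the 100 genes with the highest counts and 52.5% after correction for counts that each parent placed on the other genome. The values at mitosis were 54.0% and 52.7%. All these shares leave out unplaced genes, which took 3.42% of the counts in AA and 10.9% in BB at meiosis. More of the B transcripts than of the A transcripts may thus be missing, so the A share may be too high.

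**Figure D1:**
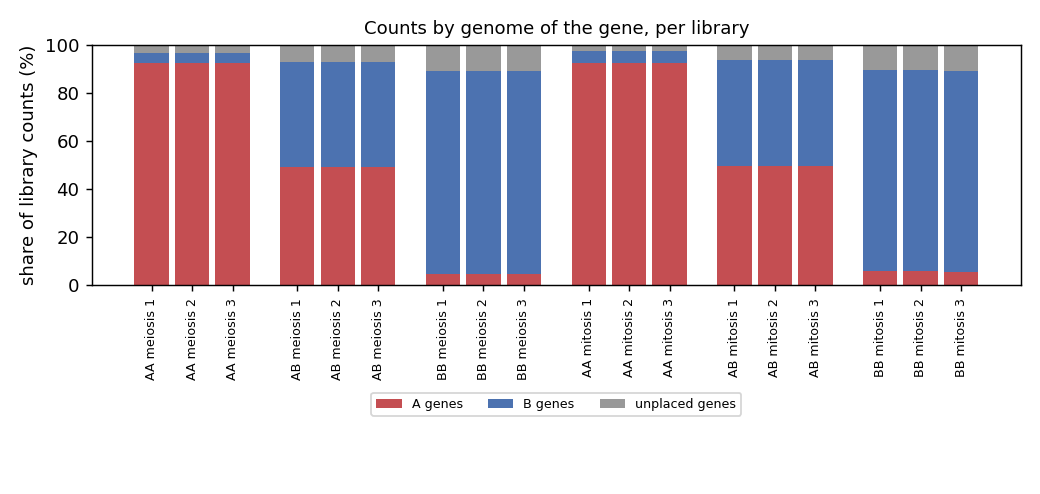
Share of each library's counts (vertical axis, %) on A genes, B genes and unplaced genes, 1 bar for each of the 18 libraries. A genes took 92.5% of the counts in AA at meiosis, 49.1% in AB and 4.84% in BB.

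The A genes were compared between AA and AB, and the B genes between BB and AB, with expression given as CPM, the counts scaled to a common total, of that genome's own counts. Levels are thus relative to the other genes of the same genome. The files do not pair the identifiers with gene names, so genes are described by genome, by their change between stages and by whether they were detected. Under this design the 2 parents were not compared with each other and AB was not compared with a mid-parent level.

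The change from meiosis to mitosis was the largest difference between the libraries. The first principal component of the AA and AB libraries over A genes held 75.4% of the variance and separated the stages, and that of the BB and AB libraries over B genes held 70.0% and did so too. In AA, of 23143 A genes tested, 9435 rose and 8681 fell at mitosis, and of these 6847 rose and 5728 fell at least 2-fold. A group of 1803 A genes rose at least 32-fold. Together these genes went from 0.149% ± 0.000735 of the A counts at meiosis to 39.7% ± 0.469 at mitosis. A second group of 730 A genes fell at least 32-fold and went from 6.71% ± 0.0497 to 0.0232% ± 0.000714 of the A counts. Expression also became concentrated in fewer genes: the 100 most abundant genes of each library took 14.8% ± 0.0586 of all counts at meiosis and 27.8% ± 0.0767 at mitosis. The number of genes that made up 50% of the counts fell from 1295 ± 4.73 to 755.0 ± 7.0.

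Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. BjuA016115 rose from 0.865 ± 0.411 to 6373 ± 301 CPM in AA, a log2 change of 12.82 (SE 0.12, edgeR adjusted p = 1.35e-28). BjuA040483 rose from 4.44 ± 0.566 to 16949 ± 1217 CPM, with a log2 change of 11.89 (SE 0.10). BjuA010165 fell from 5974 ± 143 to 1.23 ± 0.753 CPM, a log2 change of -12.23 (SE 0.18, edgeR adjusted p = 4.07e-25). BjuA017126 fell from 1028 ± 25.5 to 2.38 ± 1.14 CPM. With limma on log2(FPKM + 1), where FPKM are counts scaled by gene length and library total, the split in AA was 7060 higher and 11411 lower.

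In BB, of 21204 B genes tested, 8312 rose and 7656 fell at mitosis, of which 5823 rose and 4665 fell at least 2-fold. The 1468 B genes that rose at least 32-fold went from 0.0922% ± 0.000696 to 33.2% ± 0.589 of the B counts. The 580 B genes that fell at least 32-fold went from 10.7% ± 0.0105 to 0.0792% ± 0.0164. The 100 most abundant genes took 20.02% ± 0.0559 of all counts at meiosis and 26.3% ± 0.234 at mitosis, and the number of genes behind 50% of the counts fell from 1111 ± 2.0 to 887 ± 14.6. BjuB037819 rose from 1.23 ± 0.409 to 2079 ± 80.4 CPM and BjuB030536 from 1.69 ± 0.342 to 2787 ± 204 CPM. Their log2 changes were 10.71 (SE 0.09) and 10.67 (SE 0.10), with adjusted p = 1.83e-34 and 3.6e-34 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With limma on log2(FPKM + 1) the split in BB was 7547 higher and 8455 lower. BjuB041550 fell from 1194 ± 38.2 to 1.66 ± 0.765 CPM, and BjuB038805 from 1486 ± 87.2 to 2.58 ± 0.471 CPM.

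The AB anthers also switched between stages, in both genomes. Among A genes 9499 rose and 8428 fell at mitosis in AB, with 7138 and 5696 of them at least 2-fold. Among B genes 8302 rose and 7995 fell, with 6239 and 5426 at least 2-fold. Most genes that had changed at least 32-fold in a parent moved the same way in AB. Of the 1803 A genes that rose in AA, 1739 were also called higher at mitosis in AB, 3 lower and 61 not called. Of the 1468 B genes that rose in BB, 1375 were called higher, 9 lower and 84 not called. Of the genes that fell, 665 of 730 A genes and 545 of 580 B genes were called lower in AB. Across genes the stage changes of AB and of the parent had a Spearman correlation of 0.816 for A genes and 0.768 for B genes, where genes are not independent replicates.

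In AB the 2 measures of concentration differed. The number of genes behind 50% of the counts was 2075 ± 7.0 at meiosis and 2095 ± 25.2 at mitosis in AB, a difference within the spread between libraries. The 100 most abundant genes took 14.1% ± 0.0855 of the counts at meiosis and 16.1% ± 0.191 at mitosis, and the ranges of the libraries did not overlap, as 10% of chance splits of 3 against 3 would also give. Among A genes, BjuA005098 rose from 10.1 ± 1.14 to 13168 ± 478 CPM in AB and BjuA018244 from 1.99 ± 0.590 to 1918 ± 53.4 CPM. BjuA038096 fell from 19783 ± 240 to 2.04 ± 3.54 CPM, a log2 change of -13.18 (SE 0.25, edgeR adjusted p = 9.28e-23). All of its counts in AB at mitosis came from replicate 3, so the size of this change rests on that library, and the fitted value without it was -20.34, with 0 counts left at mitosis. BjuA010165, named above for its fall in AA, fell from 17109 ± 1495 to 9.02 ± 4.34 CPM in AB.

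Among B genes in AB, BjuB043854 rose from 2.04 ± 0.416 to 10192 ± 74.7 CPM, a log2 change of 12.27 (SE 0.09, edgeR adjusted p = 3.88e-36). BjuB017202 rose from 3.89 ± 1.53 to 4313 ± 148 CPM. In BB the same gene was already at 97.3 ± 3.77 CPM at meiosis and reached 10269 ± 110 CPM. BjuB041169 fell from 27249 ± 570 to 3.33 ± 3.73 CPM, a log2 change of -12.95 that was -14.40 without AB replicate 3 at mitosis. BjuB023991 fell from 5396 ± 133 to 1.96 ± 1.86 CPM in AB, but this gene, labelled B, was counted almost entirely in AA among the parents, with 482 CPM of all counts there against 0.0159 in BB. Its log2 change in AB was -11.38, and -12.33 without AB replicate 3 at mitosis.

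**Figure D2:**
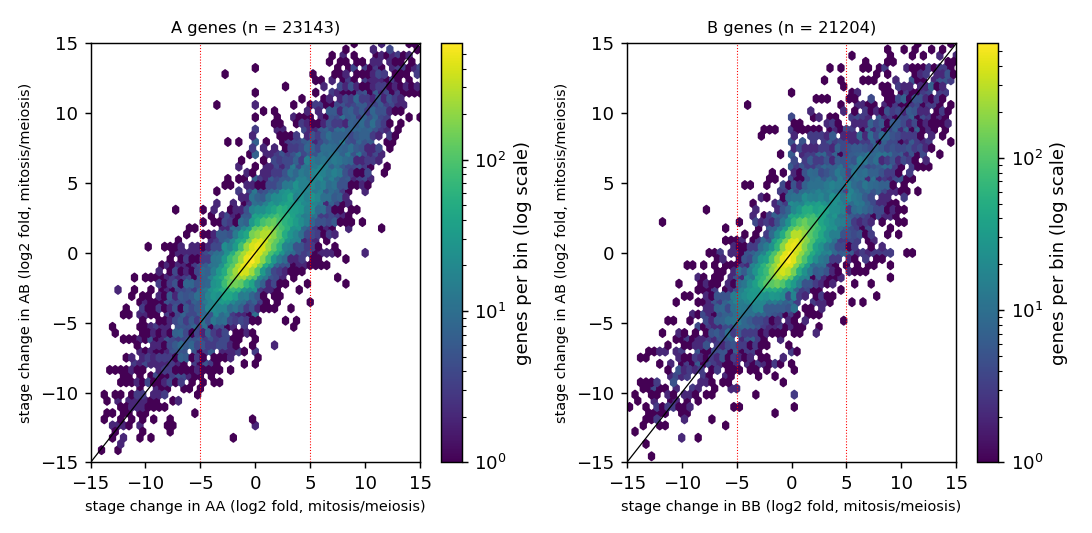
Stage change in AB (vertical axis, log2 fold of mitosis over meiosis) against stage change in the parent (horizontal axis, same unit) for 23143 A genes and 21204 B genes, as bins coloured by the number of genes on a log scale. The black line marks equal change and the dotted lines mark 32-fold change in the parent; the Spearman correlations across genes were 0.816 and 0.768.

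At meiosis, 6410 A genes were higher and 5978 lower in AB than in AA, of 23143 tested. The changes of at least 2-fold numbered 2655 higher and 2876 lower. Many of the A genes that were higher in AB were also counted in BB, where no A genome is present. When genes drawing 10% or more of their parental CPM from BB (called shared with BB below) were left out, the balance turned to 4962 higher and 5875 lower, and 1479 remained higher and 2822 lower by at least 2-fold. The called genes left out were mostly higher in AB and the rest were not scaled again, so this turn is in part by construction. Expression levels of AB and AA at meiosis had a Spearman correlation across genes of 0.880. BjuA042158 stood at 1328 ± 16.6 CPM in AB and 1.23 ± 0.356 in AA, and BjuA045063 at 1542 ± 11.97 and 4.20 ± 0.394 CPM. Both were counted mainly in BB among the parents, which held 455 and 878 CPM of all counts, against 0.670 and 4.55 in AA. BjuA021992 was lower in AB, at 2.82 ± 0.6001 against 225 ± 9.22 CPM, and BjuA025853 at 5.13 ± 1.27 against 380 ± 1.46 CPM. Their log2 differences were -6.31 (SE 0.11) and -6.20 (SE 0.10), with edgeR adjusted p = 5.42e-23 and 1.18e-23.

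The balance of higher and lower A genes at meiosis depended on the scaling. With library sizes from all genes, AB libraries carry fewer A counts by construction, and 3934 A genes were higher and 9342 lower. With limma on log2(FPKM + 1) the split was 1523 higher and 16653 lower.

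The comparison of AB with BB at meiosis covered 21204 B genes. Of these, 6760 were higher and 6705 lower in AB, of which 3782 and 3622 differed at least 2-fold. Without genes drawing 10% or more of their parental CPM from AA (called shared with AA below), the balance turned to 5777 higher and 6570 lower, and 2940 were higher and 3570 lower by at least 2-fold. Here too the called genes left out were mostly higher in AB, and the rest were not scaled again. The Spearman correlation across genes was 0.844. BjuB045212 stood at 2866 ± 14.4 CPM in AB and 7.82 ± 0.321 in BB, and BjuB047432 at 330.5 ± 5.25 and 1.30 ± 0.201 CPM. Both were again counted mainly in the other parent, with 394 and 53.9 CPM of all counts in AA. BjuB033341 was lower, at 2.36 ± 1.06 CPM in AB against 397 ± 6.43 in BB, and BjuB044057 at 2.23 ± 0.399 against 202 ± 5.21 CPM. Their log2 differences were -7.39 (SE 0.10) and -6.49 (SE 0.15), with edgeR adjusted p = 4.92e-29 and 3.56e-24. With library sizes from all genes the split was 3894 higher and 10271 lower, and with limma on log2(FPKM + 1) it was 2421 higher and 13046 lower.

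At mitosis, the genes that had switched on in the parent were the ones most often lower in AB. Of the 1803 A genes raised at least 32-fold in AA, 1309 were lower in AB than in AA at mitosis, 217 were higher and 277 were not called. Their median log2 difference was -1.23, with a middle 50% between -1.74 and -0.47, and it was -1.23 with genes at 0 counts set to the floor of 3 counts. As a group they took 26.4% ± 0.344 of the A counts in AB at mitosis, against 39.7% ± 0.469 in AA. Of the 5044 A genes raised 2- to 32-fold in AA, 2125 were lower in AB and 810 higher. Of the 10568 A genes with under 2-fold change or no call, 2347 were lower and 2902 higher, with a median of 0.05. Without genes shared with BB, 2288 of 9222 were lower and 1880 higher, with a median of -0.02, and of the raised genes 1260 of 1697 were lower and 179 higher. Chosen by a rise of at least 32-fold in AB instead, 1081 of 1778 A genes were lower in AB and 362 higher, with a median of -0.94. Chosen on replicates 1 and 2, 1030 raised A genes had a median of -1.19 in replicate 3. The libraries of a group may come from the same plants. Here and for B genes below, this choice thus removes only selection on noise between libraries.

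Of the 730 A genes lowered at least 32-fold, 231 were higher in AB than in AA at mitosis, 13 were lower and 486 were not called. The group was defined on the same AA libraries, and its direction moved with the choice of genes. Of the 585 A genes lowered at least 32-fold in AB instead, 63 were higher and 69 lower in AB than in AA at mitosis. At mitosis 344 of the 730 genes had 0 counts in AA and 205 had 0 in AB, so a median fold of this group depends on how counts of 0 are treated. The 730 genes took 0.261% ± 0.0192 of the A counts in AB at mitosis against 0.0232% ± 0.000714 in AA, and 0.150% ± 0.0166 against 0.0215% ± 0.000675 without genes shared with BB. At meiosis their share was also larger in AB, at 11.1% ± 0.160 against 6.71% ± 0.0497, although 287 of them were lower in AB at that stage and 189 higher. Chosen by their fall in AB, the direction of the calls turned, with 226 of 585 A genes higher in AB at meiosis and 155 lower. Their share was again larger in AB, at 10.4% ± 0.156 against 5.81% ± 0.0449 in AA.

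Over all A genes at mitosis, 5596 were higher and 6506 lower in AB than in AA, of which 2628 and 3012 differed at least 2-fold. Without genes shared with BB, these were 1478 higher and 2930 lower. BjuA017796 stood at 1749 ± 285 CPM in AB and 3.07 ± 1.43 in AA, and BjuA017611 at 988 ± 47.5 and 3.16 ± 1.42 CPM. The first had 2423 and the second 992 CPM of all counts in BB. BjuA017089 was lower, at 2.96 ± 1.85 CPM in AB against 67.8 ± 4.36 in AA, and BjuA035812 at 3.76 ± 0.163 against 84.8 ± 5.84 CPM. Their log2 differences were -4.49 (SE 0.22) and -4.49 (SE 0.15), with edgeR adjusted p = 2.24e-14 and 4.15e-17. The first was -5.09 without AB replicate 3. With library sizes from all genes the split was 2301 higher and 13504 lower, and with limma on log2(FPKM + 1) it was 2283 higher and 13531 lower.

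**Figure D3:**
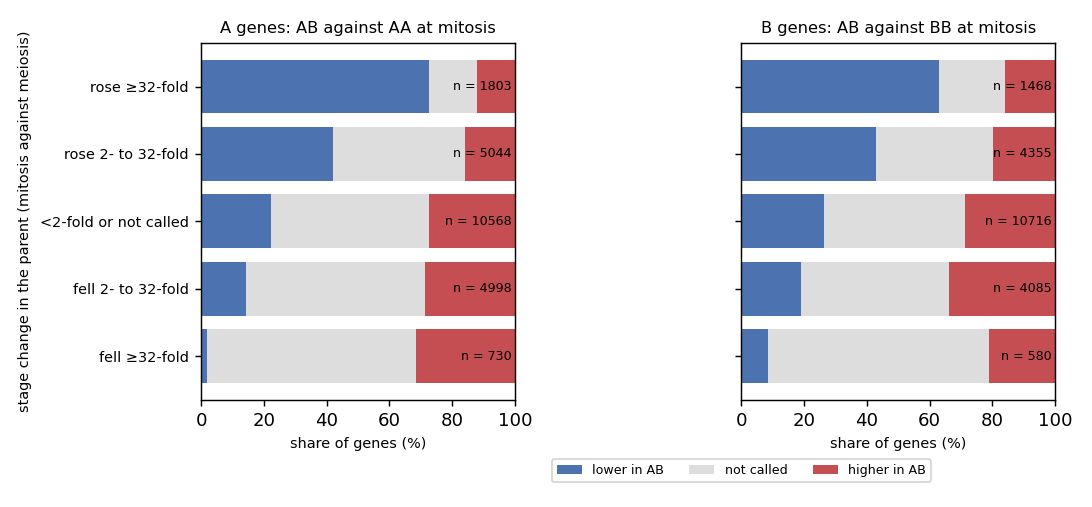
Share of genes (horizontal axis, %) called lower, not called and called higher in AB than in the parent at mitosis, for genes grouped by their stage change in that parent (vertical axis), with n genes per group. Among A genes raised at least 32-fold, 1309 of 1803 were lower in AB, and among A genes lowered at least 32-fold 13 of 730 were.

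The B genes that had switched on in BB were also lower in AB more often than higher at mitosis. Of the 1468 B genes raised at least 32-fold in BB, 926 were lower in AB than in BB, 234 were higher and 308 were not called. Their median log2 difference was -0.90, with a middle 50% between -1.63 and 0.01, and it was -0.90 with genes at 0 counts set to the same floor. They took 22.4% ± 0.282 of the B counts in AB at mitosis against 33.2% ± 0.589 in BB. Chosen by their rise in AB instead, 701 of 1447 B genes were lower in AB and 425 higher, with a median of -0.40. Chosen on replicates 1 and 2, 787 raised B genes had a median of -1.01 in replicate 3. Of the 580 B genes lowered at least 32-fold, 123 were higher in AB at mitosis, 50 were lower and 407 were not called. Chosen by their fall in AB, the direction turned, with 44 of 518 higher and 99 lower. At meiosis 333 of these 580 genes were lower in AB and 115 higher, and their share of the B counts was 8.83% ± 0.0643 in AB against 10.7% ± 0.0105 in BB. At meiosis the share of the group chosen in the parent was thus up for A genes and down for B genes, although more genes of both groups were lower than higher. Chosen by their fall in AB, the 518 B genes took 10.0% ± 0.0816 of the B counts in AB and 9.27% ± 0.00380 in BB at meiosis. With that choice 224 were lower in AB and 167 higher. The contrast of shares between the genomes thus depended on how the genes were chosen, and it was not itself tested.

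Over all B genes at mitosis, 5671 were higher and 6462 lower in AB than in BB, of which 2967 and 2957 differed at least 2-fold. Without genes shared with AA, 2118 were higher and 2918 lower by at least 2-fold. BjuB008845 stood at 4520 ± 167 CPM in AB and 6.58 ± 1.95 in BB, and was counted in AA at 5992 CPM of all counts. BjuB029109 was higher in AB, at 271 ± 20.8 against 2.08 ± 0.826 CPM, with 0.114 CPM of all counts in AA. Its log2 difference was 6.998 (SE 0.12, edgeR adjusted p = 1.08e-26). BjuB041398 was lower, at 3.97 ± 1.07 CPM in AB against 367 ± 31.6 in BB, and BjuB003031 at 10.8 ± 2.43 against 414 ± 26.8 CPM. With library sizes from all genes the split was 4425 higher and 8191 lower, and with limma on log2(FPKM + 1) it was 2219 higher and 13880 lower.

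**Figure D4:**
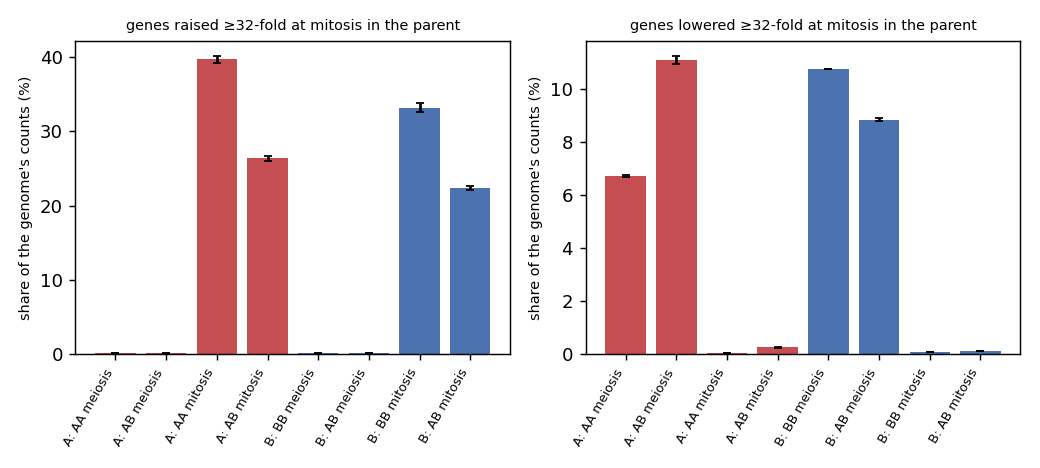
Share of the counts of one genome (vertical axis, %; mean and SD of 3 libraries) on genes raised at least 32-fold (left) or lowered at least 32-fold (right) at mitosis in the parent, for A genes in red and B genes in blue. Raised A genes took 39.7% in AA and 26.4% in AB at mitosis, and raised B genes 33.2% in BB and 22.4% in AB.

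The size of the stage change itself was tested between AB and each parent. Among A genes, 5064 had a more positive stage change in AB than in AA and 4994 a more negative one, of which 3126 and 2670 differed at least 2-fold. Among B genes the numbers were 5134 and 5012, with 3143 and 3048 at least 2-fold. BjuA021992 stayed level in AA, at 225 ± 9.22 CPM at meiosis and 224 ± 13.8 at mitosis, but rose from 2.82 ± 0.6001 to 128 ± 1.79 CPM in AB. BjuA044571 rose from 284 ± 5.45 to 764 ± 33.6 CPM in AA and from 9.78 ± 2.01 to 1367 ± 85.4 in AB. BjuA018023 rose from 1.42 ± 1.18 to 1782 ± 141 CPM in AA and from 11.5 ± 5.51 to 452 ± 19.1 in AB, a log2 difference of -4.98 that was -5.89 without AA replicate 1 at meiosis. BjuA044462 rose in AA, from 0.786 ± 0.486 to 16.2 ± 2.09 CPM, and stood at 3.09 ± 0.930 and 2.004 ± 0.597 CPM in AB, a log2 difference of -4.96 that was -5.56 without AA replicate 2 at meiosis. With limma on log2(FPKM + 1), 9663 A genes had a more positive stage change in AB and 4637 a more negative one.

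Among B genes, BjuB042898 went from 312 ± 17.404 to 180 ± 27.2 CPM in BB but rose from 7.65 ± 1.61 to 486 ± 28.8 CPM in AB. BjuB048813 was at 192 ± 3.01 and 219 ± 12.6 CPM in BB and rose from 4.08 ± 1.13 to 510.4 ± 18.8 in AB. BjuB022428 rose from 6.63 ± 1.19 to 169 ± 11.5 CPM in BB and fell from 175 ± 7.78 to 54.5 ± 3.66 in AB. BjuB003009 rose from 2.21 ± 1.08 to 39.6 ± 1.42 CPM in BB and was at 12.3 ± 0.696 and 3.77 ± 1.39 CPM in AB. The differences of stage change for these 4 genes, on the log2 scale, were 6.78 (SE 0.15), 6.77 (SE 0.12), -6.35 (SE 0.13) and -5.87 (SE 0.33), with edgeR adjusted p between 1.05e-25 and 1.26e-14.

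Genes that differed from a parent at one stage differed the same way at the other more often than independent lists would. Most of them did not do so at the 2-fold limit. Leaving out genes shared with the other parent, 282 A genes were higher in AB by at least 2-fold at both stages, against 104 for independent lists. For lower A genes the numbers were 725 and 393. Among B genes, 846 were higher at both stages against 315, and 1025 were lower at both against 528. At meiosis the lists held 1479 higher and 2822 lower A genes, and 2940 higher and 3570 lower B genes. Of these 212, 216, 264 and 189, in that order, differed at least 2-fold in the opposite direction at mitosis. Independent lists were taken over all tested genes, also those with few counts, which may raise the excess. The libraries of the 2 stages are separate, so these lists share none. One-sided Fisher's exact tests of the 4 overlaps over genes, which are not independent replicates, gave p between 2.71e-201 and 7.63e-58.

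Few genes of either parent went undetected in AB. A gene was called undetected at 3 counts or fewer over the 3 libraries of a group. Of the A genes at 10 CPM or more in AA, 10 of 11631 were undetected in AB at meiosis and 11 of 11169 at mitosis, 3 of them at both stages. Of the B genes at 10 CPM or more in BB, 64 of 10631 were undetected in AB at meiosis and 44 of 11223 at mitosis, 21 of them at both. In the other direction, 254 A genes at meiosis and 346 at mitosis were at 10 CPM or more in AB and undetected in AA. Of these, 249 and 334 had more than 3 counts in BB. For B genes the numbers were 240 and 257, of which 224 and 228 had more than 3 counts in AA.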

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

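Among the tests below, those of pollen cell number, of bud stage, of repeated sequencing runs and of library size were chosen only after the result was seen.

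The stage change differed between AB and AA in 10058 A genes and between AB and BB in 10146 B genes, by the interaction term of edgeR's quasi-likelihood fit. The named A genes with such a difference were BjuA044571 (log2 difference 5.69), BjuA021992 (5.50), BjuA018023 (-4.98, and -5.89 without AA replicate 1 at meiosis) and BjuA044462 (-4.96, and -5.56 without AA replicate 2 at meiosis). The named B genes were BjuB042898 (6.78), BjuB048813 (6.77), BjuB022428 (-6.35) and BjuB003009 (-5.87).

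Other groupings of the libraries were tried for each count of genes. For the stage changes, 2 of 40 drawn splits gave as many A genes as the real one, the real one included, so chance cannot be excluded by this count. The other split, with 11739 A genes, exchanged all AB and AA libraries at 1 stage. It therefore measures the difference between AB and AA summed over both stages, a structure of the samples. The highest count without such an exchange was 3721 A genes. For B genes 2 of 40 splits gave as many as the real 10146. The exchange of all libraries at 1 stage gave 13238 and the highest count without it was 6063. The contrasts of 3 libraries against 3 have only 10 splits, too few for a share under 0.05. In each of these, 1 split, the real one, gave the highest count, and the highest of the others was 0. The other splits mix libraries of both real groups, which widens the spread within each group and lowers the calls. The 0 is therefore no measure of chance calls, and the 3721 and 6063 above have the same limit. The real counts were 12388 and 12102 for AB against AA at meiosis and at mitosis, 13465 and 12133 for AB against BB, 18116 for the stages in AA, 15968 in BB, and 17927 A genes and 16297 B genes in AB.

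Genes raised at mitosis in a parent were lower in AB at mitosis, with medians of -1.23 (A genes) and -0.90 (B genes) on the log2 scale. Genes chosen by their rise in AB still had medians of -0.94 and -0.40, the second much closer to 0. This argues against the choice of extreme genes in the parent as the whole cause. Most of these genes, 1370 of 1778 (A) and 1012 of 1447 (B), were also chosen in the parent. Of the A genes chosen in AB, 362 were higher and 1081 lower, and of those in both lists 198 and 967. For B genes these were 425 and 701, and 202 and 597. Genes chosen in AB alone were thus more often higher than lower. The medians closest to 0 under other scaling factors were -1.17 and -0.83 (with library sizes from all genes they were -1.85 and -1.08), and without genes drawing 10% or more of their parental CPM from the other parent they were -1.27 and -0.93, which argues against both as the cause. Meiosis-stage buds mixed into the AB mitosis group would have to supply about 33.6% of the A counts and 32.6% of the B counts, but genes lowered at least 32-fold kept 2.35% and 1.38% of their meiosis share in AB. Fewer pollen cells in AB anthers (10.5% of raised A genes and 15.2% of raised B genes were higher in AB, against 20.4% and 23.7% of genes with little stage change) and AB buds at an earlier stage after meiosis (32.6% and 27.9% of lowered genes fell less in AB, many near the count floor) cannot be told apart, and a change of gene activity in the hybrid cells themselves stays open and untested.

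A signal also appeared in genes of the genome that a parent lacks. A genes counted mainly in BB numbered 1071 of 22010 and took 4.29% of the BB counts at mitosis. B genes counted mainly in AA numbered 725 of 19962 and took 3.50% of the AA counts at mitosis.

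Contamination between the parents' libraries would place a common share of all abundant genes in the other parent, but the median share of the 1000 most abundant genes was 0.0235% for A genes and 0.0773% for B genes. A candidate explanation is that such genes belong to the other genome than their label says. In AB, B-labelled genes of AA stood against AA as A-labelled genes did, with medians that differed by 0.0391 on the log2 scale, and for genes of BB the difference was -0.0043. A copy missing from the reference, with its reads placed on the copy of the other genome, would give the same values and was not tested.

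Unplaced genes were outside the comparisons and took 3.42% of the counts in AA, 7.15% in AB and 10.9% in BB at meiosis. Of 3418 unplaced genes at 1 CPM or more in a parent, 859 had over 90% of their parental CPM in AA and 2386 in BB.

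The libraries of one group lay close together, with differences beyond counting noise that grew with abundance. Between libraries of a group, the chi-square per degree of freedom of genes with 20 to 100 counts was between 2.07 and 2.45 on average. Runs of one library would give a value near 1 if each count were 1 independent read. The counting settings are not given, so this value alone cannot exclude such runs. Above 2000 counts it lay between 3.71 (AB at meiosis) and 55.9 (AA at mitosis). Library totals within a group differed by at most 9.11%. The chi-square already allows for the totals of both libraries, so a difference in size does not enter it. The 9.11% is thus no test of size as a cause of the spread. Whether the libraries came from separate plants or from one collection per group was not tested.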

How the results depend on the processing

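Leaving out genes that draw 10% or more of their parental CPM from the other parent, and all alternatives for the stage groups, were chosen after seeing the data. Apart from the minimum of 2-fold, the alternatives run kept each total of called genes within 1.5 times its main value. Such a total takes higher and lower calls together and says nothing of their split. Library sizes from all genes were run for the 4 contrasts of AB with a parent. Fits of only the groups of a contrast were run for all but the 2 differences of stage changes. The minimum of 2-fold lowers counts by construction and took 7 of 10 totals beyond that limit. These were 5531 and 5640 for AB against AA at meiosis and at mitosis, 5796 for the stage change in AB against AA, 7404 and 5924 for AB against BB, 10488 for the stages in BB and 6191 for the stage change in AB against BB. Leaving out 1 library gave 11348 to 11503 and 11059 to 11388 genes for AB against AA at meiosis and mitosis, 12695 to 12943 and 11321 to 11562 for AB against BB, and 9518 to 9754 and 9592 to 9789 for the stage changes. The stages gave 17325 to 17410 in AA, 15275 to 15375 in BB, and 17642 to 17732 A genes and 16033 to 16112 B genes in AB. The share of AB counts on A genes at meiosis and mitosis was 53.6% and 54.0% without the 100 genes with the highest counts, 52.5% and 52.7% after correction with the parents' counts, and 52.86% to 52.90% and 53.16% to 53.17% when leaving out 1 library. Among stage groups, the median of B genes lowered in the parent turned from 0.17 to -0.22 when chosen by their fall in AB, and that of A genes went from 1.28 to 0, and the cause was not tested. The calls of lowered A genes went from 231 higher and 13 lower to 63 and 69, and those of B genes from 123 and 50 to 44 and 99. These medians give no direction. Both choices gave 0.57 (A) and 0.62 (B) with counts up to 3 set to 3. Genes at this floor in both groups fix these values. Leaving out 1 library gave 0.79 (without AB replicate 3 at mitosis) to 1.37 (A) and 0 to 0.27 (B). On replicates 1 and 2 the choice gave 0.39 (262 A genes) and 0 (280 B genes) in replicate 3.

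Library sizes from all genes moved the median log2 difference of AB from AA to -0.33 at meiosis and -0.63 at mitosis, and from BB to -0.47 and -0.21, since AB libraries hold fewer counts of each genome. Upper-quartile factors moved the median stage change of A genes to -0.19 in AA and -0.06 in AB, from 0.01 and 0.10, and the difference of these changes to 0.15 from 0.04. The main splits of higher and lower calls are near even, and upper-quartile factors turned which side was larger for all 4 stage comparisons (8096 against 10204 in AA, 7849 against 8130 in BB, and 8710 against 9188 A genes and 8015 against 8276 B genes in AB). They also did so for AB against AA (5888 higher and 6536 lower at meiosis, 6223 and 5922 at mitosis) and BB at mitosis (6188 and 5905). Relative log expression factors and DESeq2 did so for AB against BB at meiosis (6687 and 6780, 6490 and 6554) and for the stage change in AB against AA (4930 and 5103, 4837 and 5114). No filter on low counts did so for AB against BB at meiosis (6702 and 7505) and at mitosis (6512 and 6381), and fitting only the groups of the contrast for AB against AA (5929 and 5598) and BB (5850 and 5626) at mitosis. So did leaving out AB replicate 1 (6470 and 6473) or 2 (6413 and 6463) for AB against BB at meiosis, and AA replicate 1 (4762 and 4788) or 2 (4759 and 4760) at meiosis, AA replicate 2 (4748 and 4770) or AB replicate 3 (4791 and 4869) at mitosis for the stage change in AB against AA. All 576 alternative values of named genes kept direction and call. These genes were chosen for the largest changes in the same data, so this says little about other genes. With the replicate number as a block the counts were 12137, 11807, 17952, 17747 and 9858 for the A genes and 13231, 11883, 15792, 16147 and 9959 for the B genes (AB against the parent at meiosis and at mitosis, the stages in the parent and in AB, and the difference of stage changes), and no pairing showed (correlations of -0.03 to 0.03). Gene list tests (no list entry matched an identifier) and comparisons between the parents and with a mid-parent level were not run. Depth limits genes near 0 counts, such as the 344 of 730 lowered A genes with 0 counts in AA at mitosis.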

Other observations

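The following values were chosen after the data were seen. At meiosis 0.602% of the B genes at 10 CPM or more in BB were undetected in AB, against 0.0860% of the A genes at 10 CPM or more in AA. At mitosis the shares were 0.392% and 0.0985%. The difference between the genomes was not tested. Among B genes 21 were undetected at both stages.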
